A study of Caenorhabditis elegans with 6 samples.

How the data were processed

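RNA was extracted from bleach-synchronized C. elegans grown on agar to the middle of the third larval stage, and libraries were made with a TruSeq kit, per the labels' protocols. The 3 WT and 3 blmp-1(tm548) samples were grouped by their titles. The authors deposited 1 table of FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of a library, with a row per feature and a column per library. TopHat2 2.0.7, Cufflinks 2.0.2 and Cuffdiff are named in the submitters' processing notes. The genome build, the annotation and any removal of duplicate reads are not given in the sources used here. For this reason no coordinates are printed. Gene symbols, biotypes and exon lengths came from tables of the WBcel235 assembly, matched on sequence names, and 44880 of 45343 features matched (21904 of 22268 above 0 in any library). No column was left without a sample.

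FPKM values are not counts, so no count model was used. Values were set to log2(FPKM + 1), and features with a mean FPKM of at least 1 over the 6 libraries were fitted with limma 3.58.1 in R 4.3.3, with the group as the single term, a trended prior variance and Benjamini-Hochberg adjustment over 17058 features. An adjusted p under 0.05 was called. A fold is on the log2(FPKM + 1) scale, which understates changes of low genes, and a gene listed at 0 throughout a group was given no fold. The percent of changed genes recovered was tested on simulated data for this comparison, over 17058 genes with 200 changed ones. It was 6.67% at a fold of 1.5, 73.7% at 2 and 90.6% at 4, with 10 false calls among 128. Small changes were thus mostly missed in the simulation. Its dispersion of 0.02 was assumed and not estimated from these libraries. The real comparison called 1092 genes, so its adjustment was less strict and these rates hold for the simulated setting only.

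Low values gave the depth. For genes with a mean below 1 FPKM, the most common ratio between libraries gave the relative worth of 1 read, and 406 single-isoform genes of 1000 to 4000 nt gave 7950000 reads for WT replicate 1. Other libraries were scaled from it. At this depth 1 FPKM on 1 kb is about 7.95 reads. These are estimates from steps, and no interval or count test was built on them. The steps were read as whole numbers within 0.5%, up to 5 reads per library. Where a single library of a group was above 0, its value was taken as 1 read whatever its size. Read numbers of such groups are set by the search and were not measured. A control of this search took pairs of a feature and a group with all 3 libraries above 0. Under 200 nt, steps were found for 57.6% of such pairs, and for 0.563% after the values were moved at random. For protein-coding genes of at least 300 nt they were found for 2.04% of such pairs, and for 0.248% after such a move. Pairs with a library at 0 match more easily and had no such control.

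Some abundant transcripts had similar values. The means of 10 such genes, among them unc-54, act-1, eef-1A.1 and rpl-3, lay between 190 and 231 FPKM after scaling by the worth of 1 read, which is 1.51 to 1.84 reads per base. Other genes stood above this level: 71 ribosomal protein genes of at least 300 nt had a median of 269 FPKM and a 95th percentile of 374. On many called features under 200 nt a single read was worth many FPKM in the group with the higher values, and often far less in the other.

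Before the data were examined, 30 gene lists were fixed from general knowledge of C. elegans epidermis, molting, developmental timing, immunity and tissue markers, and tested with camera at a preset correlation of 0.01 for lists with at least 5 tested members, adjusted over the 30 lists. Camera with an estimated correlation and fry were alternatives. The lists were cuticle collagens, furrow collagens, molting and apical matrix factors, hedgehog-related secreted proteins, patched-related proteins, heterochronic genes, molting cycle and epidermal transcription factors, distal tip cell migration and guidance, vulva development, germline, oocyte and sperm markers, vitellogenins, intestine, body wall muscle, pharynx and neuron markers, epidermal antimicrobial peptides, intestinal immune effectors, C-type lectins, osmotic and cuticle damage response, heat shock proteins, endoplasmic reticulum and mitochondrial chaperones, detoxification enzymes, ribosomal proteins, oxidative phosphorylation, DNA replication and cell cycle, fatty acid metabolism, nuclear hormone receptors and histones.

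The named genes also followed a fixed rule: 15 genes always; the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and that were above 0 in each group; and up to 3 called members with the largest change of each list that camera called. Other members of fixed lists, a ranking within protein-coding genes of at least 300 nt, and col-19 were added after the values were seen. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, median-of-ratios and quantile scaling, the replicate number as a block, a constant or robust prior, library weights, each library left out in turn, replicate 1 of both groups left out, and a log2 difference of at least 1. Added after seeing the data were protein-coding features of at least 300 nt, mean FPKM from 1 to below 100, and FPKM divided by the worth of 1 read. Gene classes of the symbol prefix were tested for enrichment with the hypergeometric (one-sided Fisher's exact) test of scipy 1.17.1, with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 under Python 3.11.15.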

Results

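Messenger RNA was sequenced from whole Caenorhabditis elegans larvae in the middle of the third larval stage (L3). There were 3 libraries from wild type (WT) and 3 from animals carrying tm548, a mutant allele of blmp-1. The gene blmp-1 encodes a zinc-finger transcription factor, the worm homolog of the mammalian repressor Blimp-1. The labels call the samples biological replicates and do not say how the cultures were kept apart. The values were gene-level FPKM. Part of the low ones lay on steps, read as the worth of 1 read. From these steps the depth came to 7950000, 7410000 and 7800000 reads in WT replicates 1, 2 and 3. It was 7860000, 7860000 and 7380000 reads in mutant replicates 1, 2 and 3. Of 45343 features in the table, 22268 were above 0 in any library and 17058 had a mean of at least 1 FPKM and were tested.

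The comparison of mutant with WT asks which transcripts of mid-L3 larvae depend on blmp-1. In the mutant, 570 genes rose and 522 fell (limma on log2 of FPKM plus 1, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Of these, 81 were features with under 200 nt of exon. For 74 of the 81 the steps gave at most 5 reads in each library of the higher group. The calls of all 81 are not read here as changes in transcript level. Protein-coding genes of at least 300 nt made up 477 of the rises and 454 of the falls. Among these falls K07C5.13, W04G5.16 and Y17G9B.2 also rested on 1.33 reads per WT library and are not read as such changes either. Read numbers of single genes are given for named genes only, and steps above 5 reads were not looked for. Other calls may thus rest on few reads as well. The clearest group was the antimicrobial peptides of the epidermis, of which 12 of 20 rose. Among the C-type lectins 23 of 131 fell and 5 rose, and single collagens, hedgehog-related proteins and detoxification enzymes moved in both directions. A log2 difference of at least 1 was reached by 256 of the genes that rose and 198 of those that fell. The count changed when a library was left out. This also lowers the power to call, here and for the single genes and lists below. It was 192 higher and 177 lower without WT replicate 2, 237 and 179 without mutant replicate 1, 209 and 187 without mutant replicate 2, and 379 and 315 without WT replicate 3. Without WT replicate 1 it was 526 and 391, and without mutant replicate 3 it was 620 and 712. With library weights it was 2005 and 2112.

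The blmp-1 transcript itself (F25D7.3) was at 70.4 ± 5.23 FPKM in WT and 38.4 ± 1.74 in the mutant (SD, n = 3). It was 1.81-fold lower on the log2(FPKM + 1) scale, with a log2 difference of -0.86 (SE 0.0715, limma adjusted p = 0.00299), and each mutant library lay below each WT library. The labels do not give the part of the gene that the allele removes, so a value over the whole transcript is only a partial check of the genotype labels. Of the other 14 developmental timing, epidermal and guidance genes fixed in advance, bed-3 and daf-9 changed. The transcript of bed-3 (F25H8.6), which encodes a BED zinc-finger factor needed for molting, fell from 72.3 ± 10 to 31.3 ± 10.2 FPKM (log2 difference -1.22, adjusted p = 0.0326). That of daf-9 (T13C5.1), a cytochrome P450 of dafachronic acid synthesis, rose from 32.9 ± 0.383 to 42.0 ± 1.41 FPKM (log2 difference 0.34, adjusted p = 0.0220). The molting receptor gene nhr-23 was at 44.7 ± 1.38 and 62.5 ± 8.62 FPKM and missed the threshold (adjusted p = 0.0536). It passed in 4 of 20 alternative settings, among them without mutant replicate 3 (adjusted p = 0.0211). The heterochronic gene lin-14 was at 67.4 ± 1.08 and 77.1 ± 5.31 FPKM (adjusted p = 0.131), and nhr-25 at 53.8 ± 1.57 and 60.2 ± 4.46 FPKM (adjusted p = 0.232). For dre-1, daf-12, lin-28, lin-29, lin-41, lin-42, hbl-1 and elt-3 the log2 differences were -0.11, 0.08, -0.06, -0.13, 0.06, -0.05, -0.06 and 0.16, with adjusted p of 0.547, 0.576, 0.620, 0.551, 0.799, 0.911, 0.752 and 0.424. In 1 of 20 alternative settings each, lin-14 and elt-3 passed (limma adjusted p = 0.0463 and 0.0398). The netrin receptor gene unc-5 was at 28.9 ± 1.11 FPKM in WT and 29 ± 0.751 in the mutant (log2 difference 0.00, SE 0.0648, adjusted p = 0.979). The call of bed-3 was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0521, 0.129 and 0.0862) and without mutant replicate 1 or 2 (0.119 and 0.0978). That of daf-9 was lost without WT replicate 2 or 3 (adjusted p = 0.104 and 0.0568) and without mutant replicate 1 or 2 (0.0701 and 0.0939).

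**Figure D1:**
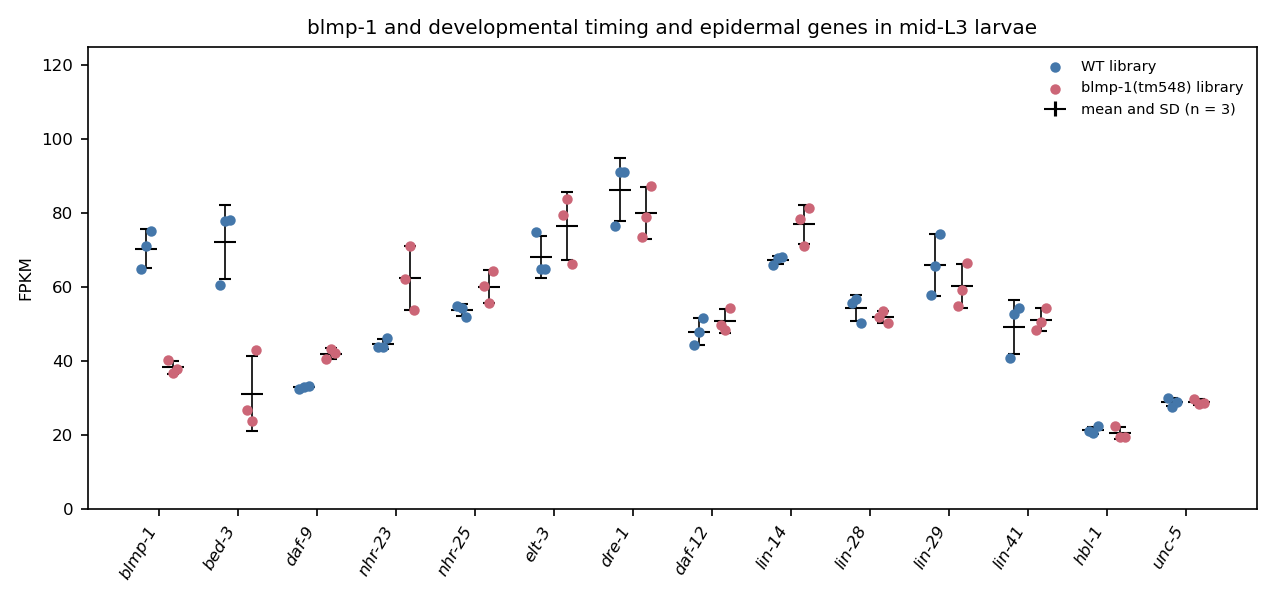
FPKM (y axis) of blmp-1 and 13 other fixed genes in each of 3 WT and 3 blmp-1(tm548) libraries, with the mean and SD of each group. The mutant means of blmp-1 and bed-3 lie at 38.4 and 31.3 FPKM against 70.4 and 72.3 in WT.

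Genes of the epidermal antimicrobial peptides, small secreted peptides induced in the skin by fungal infection and wounding, were the list with the largest share of rising members (12 of 20). The caenacin gene cnc-4 (R09B5.9) rose from 21.3 ± 3.99 to 185 ± 16.3 FPKM, cnc-2 (R09B5.3) from 22.1 ± 0.646 to 123 ± 9.59, cnc-7 (F53H2.2) from 12.5 ± 9.38 to 140 ± 15.3 and cnc-9 (R13D7.11) from 4.94 ± 3.74 to 46.1 ± 14.3. Their log2 differences were 3.07, 2.42, 3.61 and 3.12, with limma adjusted p of 0.000566, 0.000155, 0.0104 and 0.0194. Smaller rises were seen in nlp-25, nlp-27, nlp-28, nlp-29, nlp-30, nlp-31, nlp-34 and fip-5. For example, nlp-29 went from 168 ± 32.9 to 318 ± 14.5 FPKM. Some of these genes are similar copies of one another, and the counting could split reads between them. None of the 20 fell, and 13 rose when adjusted over the list alone. The list was called higher by camera (median log2 difference 0.82, adjusted p = 5.14e-10), but not with its correlation estimated from the data (adjusted p = 0.635 with an estimated correlation). The number that rose was 6 without WT replicate 2 or mutant replicate 1 and 7 without mutant replicate 2, and cnc-9 missed the threshold without WT replicate 2 or 3 or mutant replicate 1 or 3 (adjusted p = 0.0549, 0.0568, 0.0796 and 0.0506). In the overlapping list of 13 osmotic and cuticle damage genes 4 rose and 2 fell (5 and 3 adjusted over the list alone), and camera did not call it (adjusted p = 0.0662). It passed in 8 of 22 alternative settings, among them without WT replicate 1 (adjusted p = 0.0110, range over the settings 0.0110 to 0.887, the highest being the adjusted p with an estimated correlation). Without mutant replicate 1 or 2, 2 of its genes rose. Its 2 falling members were the metallothionein gene mtl-2 and the glutathione S-transferase gene gst-10.

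**Figure D2:**
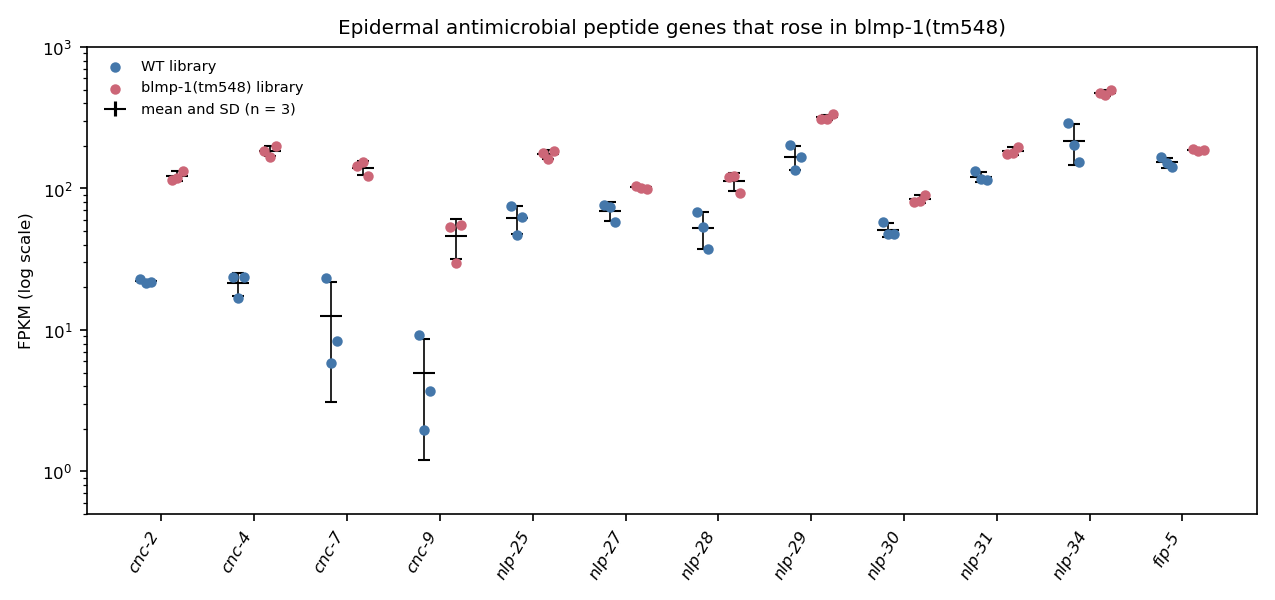
FPKM on a log axis of the 12 epidermal antimicrobial peptide genes that rose, for each of 3 WT and 3 blmp-1(tm548) libraries, with group means and SD. The mutant libraries lie above the WT libraries for each gene, with the widest gap for cnc-7 (12.5 against 140 FPKM on average).

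The C-type lectins are proteins with a carbohydrate-binding domain, of which several are made in the intestine on infection. Of 131 tested, 23 fell, 5 rose and 103 did not pass (28 fell and 8 rose when adjusted over the list alone). The largest fall was that of clec-229 (H02K04.1), from 40.7 ± 3.57 to 6.52 ± 2.96 FPKM (log2 difference -2.54, adjusted p = 0.00711), and clec-239 (Y102A5C.16) fell from 24.6 ± 7.42 to 6.42 ± 2.66 FPKM. Of those that rose, clec-174 (Y46C8AL.2) went from 1.16 ± 0.771 to 6.39 ± 2.31 FPKM (log2 difference 1.79, adjusted p = 0.0484). The call of clec-174 was lost without any single library (adjusted p = 0.0658 to 0.166), and that of clec-239 without any but WT replicate 1 (0.0547 to 0.141). Camera called the list lower (median log2 difference -0.21, adjusted p = 6.73e-05; adjusted p = 0.635 with an estimated correlation). With no filter on low values the median of the C-type lectins was -0.06 (adjusted p = 0.0177). Without WT replicate 2 or mutant replicate 2, 9 lectins fell, and without WT replicate 3 or mutant replicate 1, 11 fell. The number that rose was 3 without WT replicate 1, and 1 without WT replicate 2 or mutant replicate 1 or 2. Of 47 intestinal immune effectors 4 rose and 5 fell (8 and 13 adjusted over the list alone; camera adjusted p = 0.0729). The lysozyme gene ilys-3 rose from 4.78 ± 0.575 to 29.6 ± 11.8 FPKM, while lys-5, lys-6, spp-4, spp-25 and dod-24 fell. Without WT replicate 2 or 3, 2 rose and 3 fell, and 3 fell also without WT replicate 1 or mutant replicate 1 or 2, with at most 1 rising without the last 2. Without mutant replicate 3 camera called the list lower (adjusted p = 0.0188; adjusted p = 0.887 with an estimated correlation over all libraries).

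Among genes of the cuticle and its renewal more fell than rose. Of 146 cuticle collagens 5 rose and 12 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.0729). The collagen gene col-124 (C24F3.6) fell from 137 ± 60.6 to 7.97 ± 2.73 FPKM (log2 difference -3.86, adjusted p = 0.00636). Its WT values were 158, 184 and 68.6 FPKM in replicates 1, 2 and 3, lowest in replicate 3 as for the yolk genes. Next in size were col-88 (32.1 to 5.57 FPKM, log2 difference -2.28) and col-137 (6.94 to 1.68 FPKM, log2 difference -1.54), and col-141 rose from 14.6 ± 6.71 to 69.7 ± 17.3 FPKM (log2 difference 2.23). A mean of 100 FPKM or more was reached by 75 of the 146 collagens. Of the 71 below it, tested alone in a setting chosen after seeing the data, 1 rose and 8 fell (median log2 difference -0.29). Camera called these 71 lower (adjusted p = 0.0110). The collagen list passed camera in 5 of 22 alternative settings (adjusted p = 0.000607 to 0.887, the highest with an estimated correlation). None of the 6 furrow collagens passed limma, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.204, and 0.00769 without WT replicate 1; adjusted p = 0.887 with an estimated correlation over all libraries). With the replicate number as a block, 3 of the 6 were lower at an unadjusted p under 0.05. Camera then called the furrow list lower (adjusted p = 0.0171). Of 64 molting and apical matrix factors 5 fell and 1 rose (6 and 1 adjusted over the list alone). The genes that fell were nas-36 (C26C6.3), an astacin protease, from 71.0 ± 5.72 to 33.8 ± 6.88 FPKM, cutl-28 (F41A4.1) from 23.6 ± 4.49 to 8.38 ± 3.25, cutl-4 (W06D12.1) by 2.50-fold to 4.47 ± 0.815, bli-5 and nekl-2, and mlt-3 rose. Camera called the list lower (median log2 difference -0.15, adjusted p = 0.0113; adjusted p = 0.887 with an estimated correlation). Without mutant replicate 3, 25 collagens and 12 molting factors fell and 8 collagens rose. By limma, 0 collagens rose without WT replicate 2, mutant replicate 1 or mutant replicate 2, and 17, 12 and 11 were higher at an unadjusted p under 0.05. Without WT replicate 2 or mutant replicate 1, 5 collagens and 1 molting factor fell, and without mutant replicate 2, 6 and 3. Without WT replicate 1 or 3, 3 molting factors fell. Camera called the collagens lower without WT replicate 3 or mutant replicate 3 (adjusted p = 0.000970 and 0.00250; adjusted p = 0.887 with an estimated correlation over all libraries), and did not call the molting factors without mutant replicate 2 (0.0588). The calls of nas-36 and cutl-28 were lost without WT replicate 2 (adjusted p = 0.0695 and 0.127) or mutant replicate 1 (0.0605 and 0.123), and that of cutl-28 also without WT replicate 1 or 3 or mutant replicate 2 (0.0664, 0.0914 and 0.0817).

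Of 47 hedgehog-related secreted proteins, a family that takes part in cuticle formation and molting, 6 fell and 2 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.0729). The genes wrt-8, wrt-2, wrt-4, grd-11, grd-6 and grl-13 fell. The value of wrt-8 (C29F3.2) went from 61.2 ± 5.23 to 15.5 ± 6.94 FPKM, while grd-17 (Y102A5C.34) rose from 0.388 ± 0.336 to 10.1 ± 3.95 FPKM. Of 27 patched-related proteins che-14 (F56H1.1), which acts in apical secretion, fell from 28.1 ± 3.14 to 8.56 ± 2.49 FPKM, and ptr-22 (Y80D3A.7) rose from 2.67 ± 0.628 to 7.16 ± 1.43 FPKM (3 rose and 5 fell when adjusted over the list alone). Camera called the patched-related list lower (median log2 difference -0.26, adjusted p = 0.0333; adjusted p = 0.887 with an estimated correlation). Without mutant replicate 3, 16 hedgehog-related and 10 patched-related genes fell, and camera called the hedgehog-related list lower (adjusted p = 0.000562; adjusted p = 0.887 with an estimated correlation over all libraries). The hedgehog-related list passed camera in 7 of 22 alternative settings, among them the replicate number as a block (adjusted p = 0.0271). At most 3 hedgehog-related genes fell without WT replicate 1 or 2 or mutant replicate 1 or 2. The patched-related list was not called without WT replicate 2 or 3 or mutant replicate 1 or 2 (adjusted p = 0.0504, 0.122, 0.0839 and 0.119), nor were the patched-related proteins without replicate 1 of both groups (0.0733). The call of che-14 was lost without WT replicate 2 (adjusted p = 0.0568), and that of ptr-22 without any but WT replicate 3 (0.0584 to 0.124).

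Nuclear hormone receptors are a large family of ligand-regulated transcription factors. Of 216 tested 13 rose, 2 fell and 201 did not pass (14 rose and 2 fell when adjusted over the list alone). The receptor gene nhr-7 (F54D1.4) rose from 14.5 ± 2.94 to 26.7 ± 1.93 FPKM, and nhr-181 (F38H12.3) and nhr-244 (ZK1025.6) fell from 9.25 ± 2.29 to 2.70 ± 0.995 and from 36.1 ± 7.32 to 13.6 ± 2.63 FPKM. Camera called the list higher (median log2 difference 0.08, adjusted p = 0.0113; adjusted p = 0.887 with an estimated correlation). At most 1 receptor rose without WT replicate 2 or mutant replicate 1 or 2, and 6 rose without WT replicate 3. With the replicate number as a block 7 receptors rose and 4 fell. Camera did not call the nuclear hormone receptors without WT replicate 2 (adjusted p = 0.0555), nor with no filter on low values (adjusted p = 0.0501, range over the alternatives 0.000607 to 0.887). Without WT replicate 2 the calls of nhr-7, nhr-181 and nhr-244 were lost (adjusted p = 0.111, 0.127 and 0.0819), as they were without mutant replicate 1 (0.113, 0.115 and 0.0535), and those of nhr-7 and nhr-181 also without WT replicate 3 (0.0718 and 0.0821) or mutant replicate 2 (0.106 and 0.101). Of 73 histone genes 4 rose and none fell (4 adjusted over the list alone), and camera called the list higher (median log2 difference 0.38, adjusted p = 5.86e-07; adjusted p = 0.887 with an estimated correlation). The genes were his-9 (ZK131.3), from 22.9 ± 2.95 to 43.9 ± 4.84 FPKM, his-68, his-34 (F17E9.9), from 2.17 ± 1.40 to 11.8 ± 1.51, and his-29 (F35H10.11), from 2.17 ± 1.07 to 12.8 ± 4.64. Histone genes are near-identical copies, so the gene that gave the reads is uncertain. At most 2 histone genes rose without any single library other than mutant replicate 2. The calls of his-9, his-29 and his-34 were lost without mutant replicate 1 (adjusted p = 0.0596, 0.0925 and 0.114), those of his-29 and his-34 without WT replicate 3 (0.0568 and 0.0599), and those of his-9 and his-34 without WT replicate 2 (0.0566 and 0.0523). That of his-29 was lost also without WT replicate 1 (adjusted p = 0.0617), and that of his-34 without mutant replicate 2 or 3 (0.0923 and 0.0702).

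Of 176 detoxification enzymes 12 rose and 16 fell (24 and 34 adjusted over the list alone; camera adjusted p = 0.487), with a median log2 difference of -0.06 and a mean of 0.04. The cytochrome P450 gene cyp-33C8 (R08F11.3) rose from 24.2 ± 2.13 to 89 ± 5.29 FPKM (log2 difference 1.84, adjusted p = 0.000489), and cyp-13A5, cyp-13A8, cyp-13A12, cyp-13B1, cyp-14A4, cyp-32A1 and cyp-32B1 also rose, while cyp-25A1, cyp-35A2, cyp-35A5 and cyp-35C1 fell. The glucuronosyltransferase genes ugt-1, ugt-6, ugt-8, ugt-9, ugt-46, ugt-47, ugt-63 and ugt-65 fell, while ugt-19, ugt-41 and ugt-62 rose. Also falling was the superoxide dismutase gene sod-3. The number that fell was 3 without WT replicate 2, 7 without mutant replicate 2, and 10 without WT replicate 1 or 3 or mutant replicate 1. Of 67 fatty acid metabolism genes 4 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.204), among them the lysosomal lipase gene lipl-3 (4.52 to 1.32 FPKM) and the lipid-binding protein gene lbp-8 (13.6 to 3.8 FPKM), which both fell. Without WT replicate 2 or mutant replicate 1, 1 of the fatty acid genes fell, without mutant replicate 2, 2 fell, and without mutant replicate 3, 6 fell and 3 rose. By limma, 0 fatty acid genes rose without WT replicate 2 or 3 or mutant replicate 1 or 2 (6, 5, 3 and 3 higher at an unadjusted p under 0.05). Of 34 replication and cell cycle genes the cyclin-dependent kinase inhibitor genes cki-1 (57.8 ± 4.86 to 80.1 ± 1.89 FPKM) and cki-2 rose and none fell (2 adjusted over the list alone; camera adjusted p = 0.739). In this list 2 rose without WT replicate 1 or mutant replicate 3, and at most 1 without another library. In the list of 15 heat shock proteins hsp-43 rose and hsp-12.3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.739). By limma, 0 heat shock genes rose without WT replicate 2, mutant replicate 1 or mutant replicate 2, and 1 was higher at an unadjusted p under 0.05. Without mutant replicate 3, 2 fell.

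Among tissue markers, 1 of 27 intestine genes fell (mtl-2; 0 adjusted over the list alone), 1 of 52 neuron genes rose (flp-13; 0 adjusted over the list alone), and of 29 pharynx genes marg-1 and phat-5 rose and abu-4 fell (3 and 1 adjusted over the list alone). Their camera adjusted p were 0.204, 0.166 and 0.519. In the pharynx list the median and mean log2 differences were below 0 and camera's direction was up. The sign of the median of this list flipped under median-of-ratios and quantile scaling, as did that of body wall muscle, heat shock and oxidative phosphorylation genes. Camera called the intestine list lower without WT replicate 1 (adjusted p = 0.0271) and the neuron list higher without mutant replicate 2 (0.0452), each at an adjusted p = 0.887 with an estimated correlation over all libraries. By limma, 0 neuron genes rose without WT replicate 1, 2 or 3 or mutant replicate 1 or 2 (4 or 5 higher at an unadjusted p under 0.05). The intestine list had 0 falls by limma without WT replicate 2 or mutant replicate 1, 2 or 3 (2 to 8 lower at an unadjusted p under 0.05). In the pharynx list 0 genes rose by limma without WT replicate 2 or mutant replicate 1 or 2 (3, 4 and 6 higher at an unadjusted p under 0.05), 1 rose without each of the others, and 4 fell without mutant replicate 3. None of 26 body wall muscle, 79 ribosomal protein, 37 oxidative phosphorylation, 15 endoplasmic reticulum and mitochondrial chaperone, 25 distal tip cell and 22 vulva genes passed limma, also when adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 0, 0, 1, 2 and 3 of them, and the camera adjusted p were 0.739, 0.658, 0.488, 0.204, 0.937 and 0.204. Of the ribosomal proteins 78 of 79 had a mean of 100 FPKM or more, as had 35 of 37 oxidative phosphorylation, 19 of 26 body wall muscle and 12 of 15 chaperone genes. Some genes at such levels did reach the threshold, as col-162 with 221 ± 5.86 FPKM in WT and 157 ± 11.5 in the mutant (limma adjusted p = 0.00948). Of 2413 tested genes with a mean of 100 FPKM or more 134 passed (5.55%, against 7.68% from 10 to 100 FPKM). This count includes features that rest on few reads, such as T10H4.17 and K07C5.13. Missing the threshold does not establish that a gene did not differ. Camera called ribosomal proteins higher without WT replicate 2 (adjusted p = 0.0131) and oxidative phosphorylation lower without WT replicate 1 (0.0345), each at an adjusted p = 0.969 with an estimated correlation over all libraries. The 22 heterochronic genes held daf-9 as the single gene that passed (1 adjusted over the list alone; camera adjusted p = 0.265). In the 22 molting cycle and epidermal transcription factors bed-3 alone passed (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.267), with a median log2 difference of 0.08 and a mean of -0.05.

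Reproductive genes differed between WT libraries. Of 6 vitellogenins, the yolk proteins of adult intestine, none passed limma (4 had an unadjusted p under 0.05, and 4 fell when adjusted over the list alone), while camera called the list lower (median log2 difference -1.86, adjusted p = 0.0104; adjusted p = 0.887 with an estimated correlation). For vit-1, vit-3, vit-4 and vit-5 each mutant library lay below each WT library, as for vit-5 with 59.5, 82.0 and 15.5 FPKM in WT replicates 1, 2 and 3 and 14.5, 5.45 and 11.1 FPKM in the mutant (log2 difference -2.03, adjusted p = 0.134). The groups overlapped for vit-6 and vit-2. Of the 6 genes vit-2 had the smallest difference (log2 difference -0.72, adjusted p = 0.485). It was at 86.0, 122 and 31.5 FPKM in WT replicates 1, 2 and 3 and at 58.3, 26.3 and 47.2 FPKM in the mutant, and the adult collagen gene col-19, chosen after its values were seen, at 101, 123 and 33.5 FPKM in WT and 51.4, 34.4 and 35.9 FPKM in the mutant. Without WT replicate 3, 4 vitellogenins fell. None of 19 oocyte and 92 sperm markers passed (0 and 7 at an unadjusted p under 0.05; 0 adjusted over the list alone), with camera adjusted p of 0.0729 and 0.739. For sperm markers the median log2 difference of -0.03 and camera's direction, up, differed in sign, and the list was called lower without WT replicate 3 (median -0.43, adjusted p = 0.000970) and higher without WT replicate 2 (median 0.24, adjusted p = 0.0131). Without WT replicate 3, 3 oocyte markers fell and camera called that list lower (adjusted p = 1.67e-05). Over all libraries the sperm and oocyte lists had an adjusted p = 0.969 and 0.887 with an estimated correlation. Of 37 germline markers none passed (7 at an unadjusted p under 0.05; 0 adjusted over the list alone), while camera called the list higher (median log2 difference 0.14, adjusted p = 0.00324; adjusted p = 0.887 with an estimated correlation). It was not called without WT replicate 1 (adjusted p = 0.0688).

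**Figure D3:**
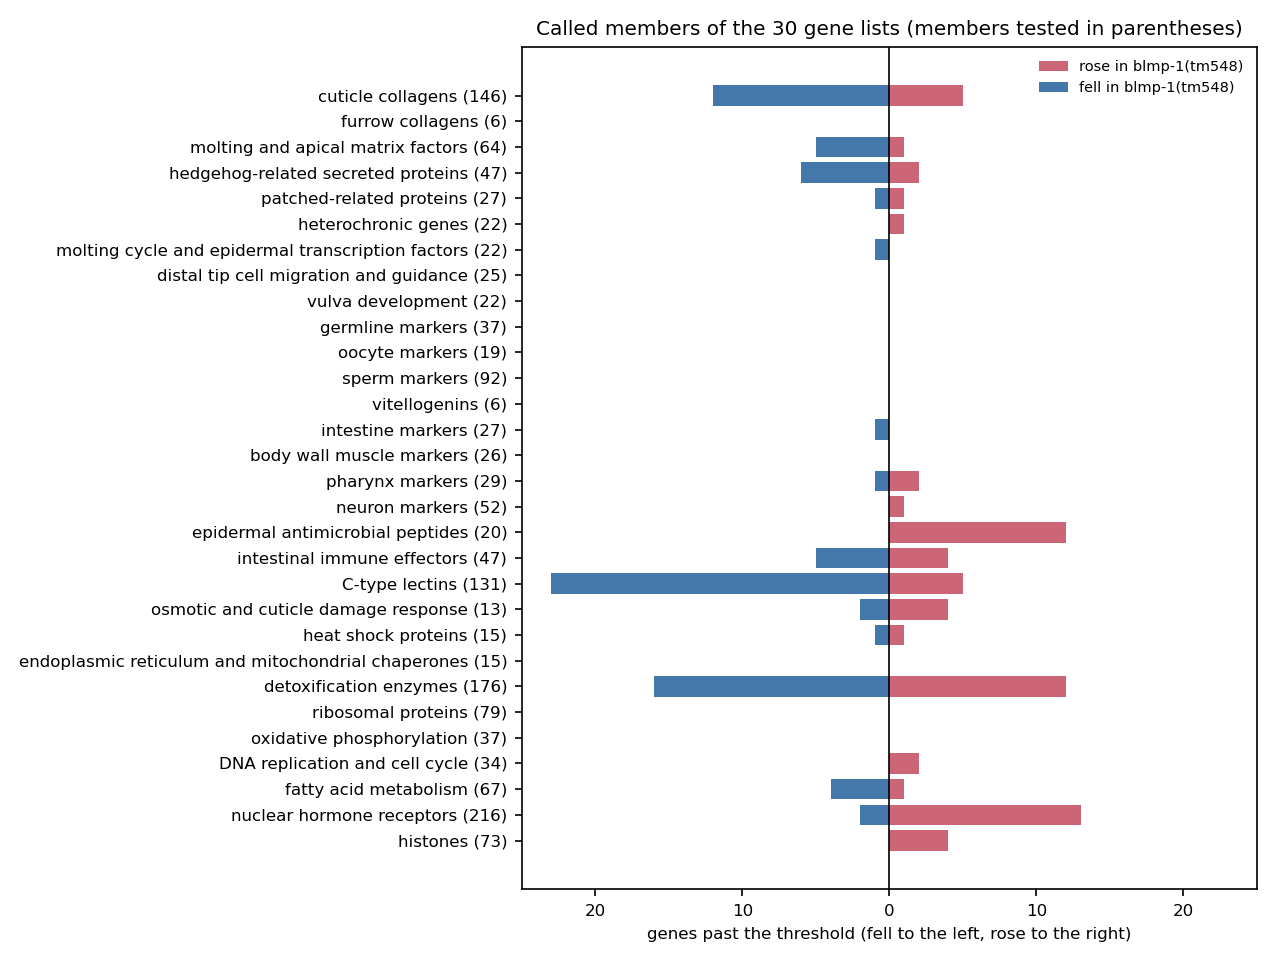
Number of genes that fell (bars to the left) and rose (bars to the right) in blmp-1(tm548) for each of 30 gene lists, with the number tested in parentheses. C-type lectins hold 23 falling and 5 rising genes, and epidermal antimicrobial peptides 12 rising and 0 falling genes.

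**Figure D4:**
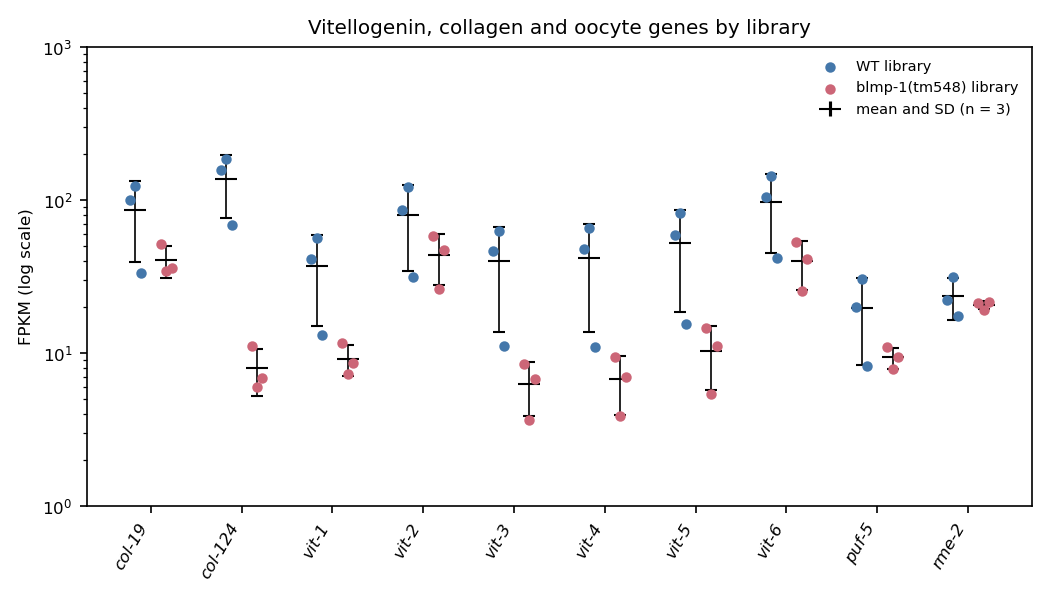
FPKM on a log axis of 6 vitellogenin, 2 collagen and 2 oocyte genes in each of 3 WT and 3 blmp-1(tm548) libraries, with group means and SD. For col-19 the WT libraries spread from 33.5 to 123 FPKM, and the mutant libraries from 34.4 to 51.4.

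The fixed ranking by size of change was mostly made of very short features: 9 of the 10 largest rises and 8 of the 10 largest falls had under 200 nt of exon. The small nuclear RNA gene T10H4.17 was listed at 1.05 ± 1.83 FPKM in WT and 652 ± 320 in the mutant, which by the steps were worth 0.333 and 2 reads per library. The protein-coding gene K07C5.13, of 654 nt, was listed at 8079 ± 3420 FPKM in WT, worth 1.33 reads per library, and 0.417 ± 0.722 in the mutant, worth 0.333 reads per library. The others were D2096.14, F43G9.15, R07E4.9, T04C9.10, F25H5.9, R151.11, F10D7.9, K08E4.12 and Y39A3B.7 among the rises and F36H1.13, T03E6.13, F25H8.8, F31B12.9, F59C6.15, Y71A12B.21, C54G7.14, C10C6.8 and fbxa-6 among the falls. In these rankings, the lower group of the features under 200 nt was worth 0.333 to 1.67 reads per library. A value of 0.333 reads came from a single library above 0, which the search takes as 1 read whatever its FPKM. For Y71A12B.21, listed among the falls in FPKM, the steps gave 1.33 reads per library in WT and 1.67 in the mutant. Within protein-coding genes of at least 300 nt, a ranking chosen after the values were seen, Y39A3B.7 rose from 0.519 ± 0.511 to 42.7 ± 11.7 FPKM, F59A6.10 from 0.582 ± 0.531 to 34.6 ± 4.65, and the insulin-like peptide gene ins-20 (ZK84.7) from 0.928 ± 0.439 to 35.5 ± 7.33. The astacin protease gene nas-10 (K09C8.3) rose from 0.187 ± 0.0449 to 20.5 ± 4.34 FPKM (log2 difference 4.16, adjusted p = 0.000582). The other rises in this ranking were F12A10.9, B0563.9, suex-1, fipr-24, C27B7.9 and F32G8.3. The F-box gene fbxa-6 (cTel54X.1) fell from 30.2 ± 4.16 to 0.0973 ± 0.0953 FPKM (log2 difference -4.83, adjusted p = 0.000225), T09D3.8 from 33.2 ± 0.917 to 0.933 ± 0.569, K02E2.8 by 12.8-fold to 9.80 ± 4.79 and C04G6.2 from 93.9 ± 5.21 to 10.8 ± 4.01. The other falls were K07C5.13, col-124, nspb-3, B0034.7, W04G5.16 and Y17G9B.2. By the steps W04G5.16 (398 nt) was at 10.9 FPKM for 1.33 reads per WT library and 0.407 FPKM for 0.667 reads per mutant library. Y17G9B.2 (306 nt) was at 9.38 FPKM for 1.33 reads and 0.381 FPKM for 0.333 reads. In these genes and K07C5.13 the worth of 1 read differed between the groups. Their calls are not read as changes in transcript level. Of the genes past the threshold 18 were listed at 0 in each WT library and 16 in each mutant library, and these were given no fold. The calls of C54G7.14 and Y17G9B.2 were lost without WT replicate 2 (adjusted p = 0.0626 and 0.0565) or mutant replicate 2 (0.0553 and 0.0567), and that of nspb-3 without WT replicate 2 or mutant replicate 1 (0.0577 and 0.0529).

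Libraries correlated with r of 0.921 to 0.959 within WT, 0.940 to 0.951 within the mutant and 0.855 to 0.930 between groups, across genes, which are not independent replicates. The first principal component held 44.9% of the variance and separated WT from mutant, and the second held 21% and set WT replicate 3 (-50.5) apart from WT replicates 1 and 2 (35.4 and 35.7). The correlations and components used all 17058 tested features, 829 of them under 200 nt. On part of these the worth of 1 read differed between the groups, and its share in the separation was not tested. Camera called 8 of 30 lists, and with an estimated correlation 0 were called and 2 had an unadjusted p under 0.05. By fry, which tests the members of a list on their own, 3 lists passed the directional test and 19 the test for changes in either direction. Of the 3, the C-type lectins (23 fell, 5 rose) and the osmotic and cuticle damage list (4 rose, 2 fell) held called genes of both directions.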

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

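Alternatives not fixed in advance were the protein-coding, low-level and worth-of-1-read settings. The log2 difference of blmp-1 kept its direction and passed in 20 of 20 alternatives (-0.95 to -0.81; without single libraries -0.91 to -0.81). The counts of 570 higher and 522 lower genes stayed within 1.5 times under both pseudocounts, both filters, all 3 scalings, both priors and the protein-coding and low-level settings. They were 2005 and 2112 with library weights, 256 and 198 at a log2 difference of at least 1, and 181 and 117 without replicate 1 of both groups, where fewer libraries are left and 60.7% of calls were higher against 52.2%; the causes of the other moves were not tested. Without single libraries they ranged from 192 to 620 higher and from 177 to 712 lower; the lowest came without WT replicate 2 and the highest without mutant replicate 3. Whether replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated weakly, at 0.13, -0.035 and 0.07, but 4 of 6 libraries correlated best with their own number. The sample letters are A and B for replicate 1 of both groups and G to J for the others, and the labels do not say whether they mark batches. With the number as a block, 504 genes were higher and 425 lower. The number of lists called, 8, was 20 with library weights, 13 with quantile scaling, 13 with FPKM divided by the worth of 1 read, 3 with fry and 0 with an estimated correlation, and 7 to 11 without single libraries; the cause was not tested. Past the threshold, ribosomal proteins turned from higher to lower with library weights (median -0.0499) and sperm markers without WT replicate 3 (median -0.431; 0.240 without WT replicate 2); the cause was not tested. Short of it, 10 gene values and 42 list medians changed sign. Of 1333 values of named genes under the alternatives, 7.8% lost and 6 gained a call. The 1333 include genes not called in the main fit, which could not lose a call, and short features not read as changes. By gene the lost calls ranged from 0 of 20 settings, as for ins-20, to 13 of 19 for clec-174. Depth of 7380000 to 7950000 reads limits genes of low level and short features.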

Other observations

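The tests of gene classes and of oocyte markers were chosen after the results were seen, as was the limit of 5 reads below, and runs of neighbouring genes had been noticed before they were counted. The 14955 protein-coding genes of at least 300 nt were grouped by the class in their symbol. The carboxylesterase, chitinase-like and pals classes lay outside the fixed lists. The other classes below overlap with these lists and count the same calls again. Of 206 classes with 8 or more tested genes, carboxylesterases held 9 falling genes of 29 (0.878 by chance, adjusted p = 2.39e-05, one-sided Fisher's exact test), among them cest-1.1, cest-3 and cest-33, and 1 rising gene, cest-8 (0.925 by chance). The chitinase-like class held 4 falling genes of 14 (chil-19, chil-21, chil-22 and chil-23; adjusted p = 0.0347) and 1 rising gene, chil-24 (0.447 by chance), and the pals class, whose genes respond to intracellular infection, 5 rising genes of 21 (pals-6, pals-23, pals-26, pals-27 and pals-34; adjusted p = 0.0329). Among C-type lectins 22 of 128 fell (adjusted p = 1.49e-08) and 5 rose (4.08 by chance). Of 61 cytochrome P450 genes 8 rose (adjusted p = 0.0347) and 4 fell (1.85 by chance), and of 61 glucuronosyltransferases 8 fell (adjusted p = 0.0329) and 3 rose (1.95 by chance). In the collagen class 12 genes fell (3.79 by chance, adjusted p = 0.0329) and 5 rose (3.99 by chance), where camera had not called the collagen list (adjusted p = 0.0729). Of 72 genes of the nlp class 9 rose (adjusted p = 0.0329) and 1 fell (2.18 by chance). Among the 9 were nlp-25, nlp-27, nlp-28, nlp-29, nlp-30 and nlp-31 of the antimicrobial peptide list. Of 205 nuclear hormone receptors 13 rose (6.54 by chance, adjusted p = 0.427). Genes are not independent, and these p-values treat them as if they were.

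Called genes lay side by side on the chromosomes. Of neighbouring protein-coding genes, 91 pairs had changed in the same direction and 26 in opposite directions, against a median of 29 same-direction pairs and a highest of 50 in 10000 shuffles of the calls (permutation p = 0.0001, one-sided, the smallest that these shuffles can give). Among the 11 runs of 3 or more were C37A5.6, C37A5.5, fipr-23, C37A5.3, fipr-22 and fipr-24, and nlp-31, nlp-30, nlp-29, nlp-28 and nlp-27, which rose, and chil-19, chil-21, chil-22 and chil-23, which fell. A random spread over the gene order is argued against by these values. Shared control and reads shared between similar copies were not tested apart.

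Of the 10 ways to split the 6 libraries into 3 and 3, 1 called as many genes as the real one, itself, with 1092 genes, and the highest other called 11. With 10 splits a share under 0.05 cannot be reached.

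A set of 10 abundant genes shared a level of 190 to 231 FPKM, and this may come from a step that counted reads starting at the same position once. The level stood at a median of 1.63 reads per base over 10 abundant genes, inside the range set for such a step before the test was run. Dividing by the worth of 1 read lowered its variation across libraries from 3.57% to 0.964%. Against 1 shared level stand 71 ribosomal protein genes with a median of 269 and a 95th percentile of 374 FPKM, and 71 protein-coding genes of 300 to 500 nt and 38 of 500 to 800 nt above 250 FPKM (5, 4 and 1 in the 3 classes of longer genes), so the explanation stays open. The processing notes used here name no such step, and no biological explanation was tested.

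Most of the largest factors belonged to short features, and they may reflect 1 or a few reads. The largest of the fixed ranking, that of K07C5.13 (log2 difference -12.5), belonged to a gene of 654 nt, with 1.33 reads per WT library. In 74 of 81 called features under 200 nt, the values of the higher group were whole multiples of a step of at most 5 reads, with a median of 1.67 reads per library. In the 54 with steps in both groups, 1 read was worth 22.4 times more FPKM in the higher group than in the lower one (median). Where the lower group had a single library above 0, its value was taken as 1 read, so part of this ratio is set by the search. Such a ratio may point to how the values were scaled in each group. With it the FPKM of the groups do not compare reads, so these calls are not evidence of a change in transcript level, and none is excluded.

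The WT libraries differed in yolk, oocyte and sperm genes, and younger animals in WT replicate 3 than in WT replicates 1 and 2 are a candidate explanation. Of the 19 oocyte markers 73.7% were lowest in WT replicate 3 among the 3 WT libraries, as were 80.4% of 92 sperm markers and 6 of 6 vitellogenins, but 8.11% of 37 germline and 3.85% of 26 body wall muscle markers. Such ranks cannot tell which WT libraries departed from the labelled stage. The median log2 deviation of vitellogenins was 1.36, 1.80 and -0.393 in WT replicates 1, 2 and 3, and -1.42 to -0.499 in the mutant. For sperm markers it was 0.117, 0.657 and -0.682, and -0.226 to 0.218 in the mutant. Whether a shift in developmental time between the groups lies behind the genes called with the mutant cannot be told apart from an effect of blmp-1. The difference between WT libraries and that of the mutant were computed with no library shared. Across the 1092 called genes their Spearman rho was -0.20 and -0.0012 in the 2 pairings with WT replicate 3 in the WT difference. It was -0.21 in the pairing of WT replicate 2 minus 1 with the mutant minus WT replicate 3. Called genes had been selected partly for a small spread within the groups, so these correlations cannot decide the question. No larvae of another age were sequenced here to settle it.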
